A study of Lactococcus lactis subsp. lactis with 6 samples.

How the data were processed

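RNA of Lactococcus lactis subsp. lactis TOMSC161 was depleted of ribosomal RNA and sequenced in 6 libraries. Per the labels, these come from 3 fermentation runs, each sampled once in early and once in late stationary phase. Per the submitters' processing notes, reads were examined with FastQC (version not given), aligned with Bowtie 0.12.9 and compared with DESeq2 (version not given). The read counter, annotation version, genome build, strand setting and filters are not given in the sources used here. The signal values are normalized counts, that is gene counts divided by a size factor per library, as the authors deposited them. The log2 fold changes and their standard errors in the deposited table come from the authors' DESeq2 fit, per the file headers. The p-values and adjusted p-values of the deposited table come from the same fit by the authors, and are empty for 403 genes.

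Values in each library were whole multiples of the worth of 1 read, with 100% of them whole within 0.01, which gave the reads in listed genes. These were 7201135, 6205661 and 5703076 in the early libraries of runs 1 to 3 and 4912805, 6346446 and 4381568 in the late ones. The smallest value of a library stood for 3 to 7 reads. The table lists 2117 genes on 56 sequence fragments of a draft and no gene with a mean under 47.4. Its numbering of coding sequences runs up to 2743, so some are left out, for reasons not given in the sources used here. Shares and gene lists therefore cover the listed genes only. Coordinates are printed as deposited. The difference of end and start was a multiple of 3 in all 2117 genes, so the lengths are coding lengths. Whether positions count from 0 or from 1 is not given in the sources used here. Neighbouring genes that overlap and near-identical copies of mobile elements can share reads. The available reference table of gene names covers another strain and matched 0 of the locus tags, so gene names come from the product text of the deposited table.

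Late and early libraries were compared with limma 3.58.1 in R 4.3.3 on log2 of the normalized count plus 1, with a trend in the variance. Fold changes are therefore on that scale and understate the change of low genes. Genes needed a value of at least 10 in at least 3 libraries, which removed 0 genes. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg). Gene lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 31 lists, 30 were tested. The lists, the design and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls among called genes with a product name, the same direction in all 3 runs and a group mean of at least 50, up to 4 genes per list by adjusted p, and 24 fixed symbols. Of those symbols, 23 were matched, at 28 loci, and cspD was not. Other genes, such as ferrous iron transport protein B and the genes of neighbouring runs, were chosen after their values were seen. Because the table holds no gene symbols, list members were found by product text. False matches were removed by hand and 3 missed members added after the data had been seen.

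The fermentation run marks a shared culture per the labels, so its number pairs the libraries. Deviations of paired libraries from their group means had correlations across genes of -0.12, -0.18 and 0.04. The alternatives tried were the run as a block, pseudocounts of 0.5 and 8, no filter and a stricter filter of 50, median rescaling, quantile normalization, limma without the trend, a minimum absolute log2 fold change of 1, an adjusted p under 0.01 and leaving out each library. Limma voom on the recovered reads was added after the data were seen. The comparison was tested on simulated data for 2116 genes, with 200 of them changed. At 2-fold it recovered 64 of 100 genes and at 4-fold 94 of 100, and it called 7 of 1916 unchanged genes. Simulated genes varied independently and with the same dispersion in both groups. The real libraries differ in both respects, so these shares need not hold for them.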

Results

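Gene expression was measured by RNA sequencing, after depletion of ribosomal RNA, in stationary-phase cells of the dairy bacterium Lactococcus lactis subsp. lactis TOMSC161. Cultures were grown in bioreactors of 5 L at 30 °C and pH 6.2, with 60 g/L lactose and 15 g/L yeast extract and stirring at 200 rpm. Each of 3 fermentation runs gave 1 library from early and 1 from late stationary phase, so that each group held 3 libraries (n = 3). The title of the series places this comparison in a study of aerobic metabolism, oxidative stress and resistance to freeze-drying and storage. Values are the authors' normalized counts of 2117 genes of a draft assembly, whose build is not given in the sources used here. Positions are given by the number of the sequence fragment. The reads in these genes, worked out from the steps of the values, ranged from 4381568 in the late library of run 3 to 7201135 in the early library of run 1. A gene at the median of its library rested on 501 to 913 reads. The first principal component of the log2 values held 55.1% of the variance and separated the early from the late libraries. Late libraries resembled one another more closely (Pearson correlation across genes 0.968 to 0.991) than early libraries did (0.930 to 0.948), and 73.4% of genes had the larger SD among the early libraries.

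Normalized counts are relative to the other listed genes and do not give transcript per cell. On that scale, transcript of an NADH oxidase, which reduces oxygen with NADH, was far higher in late stationary cells. So was that of a thioredoxin reductase, which keeps protein thiols reduced. Genes for copper export and for ferrichrome and ferrous iron uptake rose with them, as did the storage and DNA-binding protein Dps and the aerobic ribonucleotide reductase. A second NADH oxidase gene and a thiol peroxidase gene fell. Transcripts fell for the dlt operon, whose products attach D-alanine to teichoic acids of the wall, and for 7 of 9 genes of leucine, isoleucine and valine synthesis. Those for ATP synthase, for 9 of 14 genes of fatty acid synthesis, for the ATP-binding genes of oligopeptide uptake and for 20 of 53 ribosomal proteins fell as well. In all, 672 of 2117 genes (31.7%) differed between late and early cells with limma at an adjusted p under 0.05, 334 of them higher and 338 lower in late cells, and 316 of them by at least 2-fold (156 higher, 160 lower). With the fermentation run as a block, 231 genes were higher and 223 lower. Without the late library of run 1, limma called 180 higher and 187 lower, without that of run 2, 208 and 206, and without that of run 3, 222 and 239. With limma voom on the recovered reads (chosen after seeing the data), which differed from limma here in both the scaling, to total reads, and the model, the median of all genes was -0.15 on the log2 scale and the calls were 248 higher and 403 lower. The p-values measure the spread between these cultures alone.

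**Figure D1:**
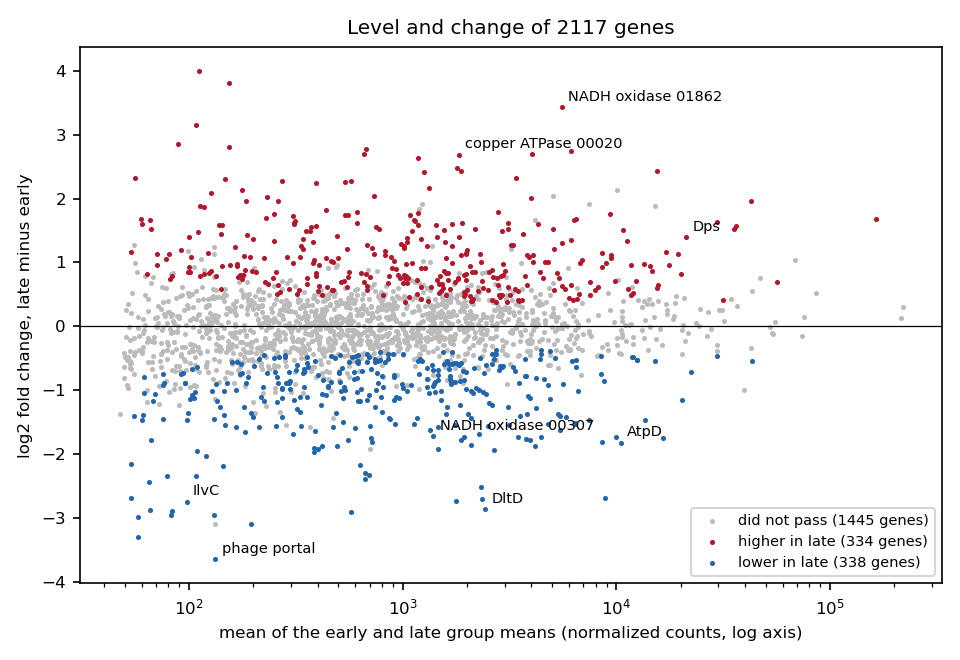
Each point is 1 of 2117 genes, with the mean of the early and late group means in normalized counts on a log axis (x) and the log2 fold change of late minus early cells (y). Red points are the 334 genes higher and blue points the 338 genes lower in late cells by limma at an adjusted p under 0.05, and grey points did not pass, and NADH oxidase O208_01862 stands at 3.43 and the phage portal gene O208_00267 at -3.64.

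The largest rises were those of a tRNA-binding protein (O208_01861), from 13.5 ± 8.06 to 208 ± 65.2 normalized counts (SD, n = 3; log2 fold change 3.99, limma adjusted p = 0.0022), and of a predicted cell-wall-anchored protein SasA (O208_00658), from 20.0 ± 5.72 to 289 ± 61.8 (log2 fold change 3.80, limma adjusted p = 0.00039). The former lies directly beside the NADH oxidase gene O208_01862 on fragment 15 (start 111801, end 113142), whose transcript rose from 963 ± 291 to 10133 ± 272 (10.8-fold, log2 fold change 3.43, SE 0.21, limma adjusted p = 0.00028). Further large rises were those of a 3-ketoacyl-CoA thiolase (O208_01353, 8.89-fold), of carbon starvation protein A, a peptide or pyruvate transporter in other bacteria (O208_01844, 6.83-fold), and of a replication protein (O208_01508, 6.69-fold), with limma adjusted p of 0.0021, 0.0030 and 0.00097. On the other side, an ABC transporter permease and substrate-binding protein (O208_01391) fell from 3083 ± 382 to 460 ± 22.6 (log2 fold change -2.74, SE 0.13, limma adjusted p = 0.00013). A cyclic-nucleotide phosphodiesterase gene (O208_01160) fell from 4076 ± 1267 to 612 ± 118 (log2 fold change -2.70, limma adjusted p = 0.0010). The same direction in all 3 runs was a condition for naming these genes, and each passed without any 1 library. Of the 111 named genes that passed, 77 did so without any 1 library. The naming rule used the size or adjusted p of genes in these data, so that share need not hold for all called genes.

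Among 21 genes of oxidative stress defence and thiol redox, 6 rose and 4 fell (7 and 4 adjusted over the list alone). Besides NADH oxidase O208_01862, thioredoxin reductase (O208_02378) rose from 175 ± 13.6 to 1149 ± 136 (6.50-fold, limma adjusted p = 0.00013), the glutaredoxin-like NrdH (O208_01054) 2.87-fold and Dps (O208_01604) from 11588 ± 499 to 30785 ± 5529 (limma adjusted p = 0.00056 and 0.0014). A second NADH oxidase gene (O208_00307) fell from 2138 ± 447 to 649 ± 123 (log2 fold change -1.72, limma adjusted p = 0.0020), so that the 2 genes of this name moved in opposite directions. Manganese superoxide dismutase (O208_01845), which removes superoxide, was already among the abundant transcripts and went from 43377 ± 11538 to 69129 ± 8957 (log2 fold change 0.70, limma adjusted p = 0.044). That call was lost with the run as a block (adjusted p = 0.092) and under median rescaling (0.052). It was also lost without any 1 library other than the early library of run 2 (limma adjusted p 0.086 to 0.146). Alkyl hydroperoxide reductase, a peroxide scavenger, did not pass for AhpC (O208_01120, log2 fold change 0.42, limma adjusted p = 0.056) or AhpF (O208_01119, 0.47, 0.185), although without the early library of run 2 the value for AhpF was 0.77 (0.0038). As a set the list was not called by camera (adjusted p = 0.147), and was called without the early library of run 2 (0.038). Fry called the list (adjusted p = 0.034), but not with the run as a block (0.170). The list of respiration and menaquinone synthesis, of 23 genes, had 3 higher and 3 lower members, and as many adjusted over the list alone (3 higher and 1 lower with the run as a block; camera adjusted p = 0.771), with both NADH oxidases among them. The prenyl diphosphate synthase genes O208_00647 and O208_01297 rose 1.59-fold and 1.75-fold (limma adjusted p = 0.0087 and 0.0099). Of 16 genes for carbon control and stationary-phase regulation, 4 rose and 1 fell, as they did adjusted over the list alone (2 and 0 with the run as a block; camera adjusted p = 0.576). The redox-sensing regulator of the Rex type (O208_01019) rose 2.46-fold (limma adjusted p = 0.0090). CodY (O208_01321), which senses branched-chain amino acids, CcpA (O208_02379) and RelA (O208_00511) had log2 fold changes of 0.15, 0.03 and -0.25 and did not pass. Leaving out the early library of run 2, 10 oxidative stress genes were higher, and the respiration list had 5 higher and 4 lower. Without the early library of run 1 or any 1 late library, the respiration list had 1 lower member and the regulators had 2 higher. The regulators had 0 lower without the late library of run 1 or run 3.

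Metal transport and iron-sulfur assembly had 16 of 30 members higher and 2 lower (16 and 2 adjusted over the list alone; camera adjusted p = 4.9e-05, adjusted p = 0.743 with an estimated correlation). Its leading members included neighbouring copper genes on fragment 54. Adjacent entries annotated as copper ATPases count as separate members, and whether they are parts of a single gene was not tested. The copper-operon repressor (O208_00021, start 6588, end 7095) rose from 1081 ± 63.9 to 7020 ± 530, and the short coding sequences O208_00020 and O208_00019, annotated as copper ATPases, rose 6.44-fold and 5.57-fold (each with a limma adjusted p = 0.00013). The ferrichrome transport ATPase FhuC (O208_01131), which takes up iron bound to a siderophore, rose from 327 ± 37.3 to 2035 ± 153 (limma adjusted p = 0.00013). Ferrous iron transport protein B (O208_01293) rose from 618 ± 212 to 1488 ± 223 (log2 fold change 1.32, limma adjusted p = 0.015). The lower members of the list were 4 without the early library of run 2.

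All 8 subunits of the ATP synthase, which couples ATP to proton movement across the membrane, fell, with a median log2 fold change of -1.72 (8 adjusted over the list alone; camera adjusted p = 2.8e-06, adjusted p = 0.743 with an estimated correlation). Its beta chain (O208_01374, fragment 0, start 42024, end 43434) went from 16382 ± 1960 to 4630 ± 469 and its alpha chain (O208_01371) from 25626 ± 3933 to 7609 ± 616 (limma adjusted p = 0.00044 and 0.00056). Fatty acid synthesis had 9 of 14 members lower and none higher (11 lower adjusted over the list alone; camera adjusted p = 0.00069, adjusted p = 0.767 with an estimated correlation). Subunits of acetyl-CoA carboxylase, which makes malonyl-CoA, were among them. The beta chain of its transferase (O208_02593) went from 2037 ± 704 to 635 ± 74.8 and the biotin carboxylase (O208_02594) from 1709 ± 522 to 614 ± 47.6 (limma adjusted p = 0.0048 and 0.0045). The dehydratase FabZ gene O208_02596 fell 2.72-fold (limma adjusted p = 0.0069), and FabH (O208_02602, log2 fold change -0.66, limma adjusted p = 0.181) and FabI (O208_00578, -0.45, 0.056) did not pass. FabH passed without the early library of run 2 (-1.07, 0.0043), and FabI under quantile normalization (0.047) and voom (0.022). Of the fatty acid synthesis list, 7 members were lower with the run as a block.

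Cyclopropane fatty acid synthase (O208_02537), which modifies membrane lipids in stationary cells of many bacteria, had 15896 ± 1250 normalized counts in early and 12331 ± 1260 in late cells (log2 fold change -0.37, limma adjusted p = 0.070). It passed in the same direction under quantile normalization (adjusted p = 0.037), with voom (0.035) and without the early library of run 2 (0.041). The authors' DESeq2 fit also called it lower (adjusted p = 0.011). None of the 11 genes for membrane lipid modification and phospholipids passed, nor did any adjusted over the list alone (1 higher and 2 lower at an unadjusted p under 0.05, 1 lower with voom; camera adjusted p = 0.576). In that list, 3 genes were lower without the early library of run 2, 1 was higher without that of run 3 and with median rescaling, and 1 was lower under quantile normalization. The authors' fit called diacylglycerol kinase (O208_00990) higher and phosphatidate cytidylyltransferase (O208_00310) lower (DESeq2 adjusted p = 0.0074 and 0.013). None of the 4 osmoprotectant transport genes passed either, again also adjusted over the list alone (1 lower at an unadjusted p under 0.05 and 1 lower with voom and under quantile normalization; camera adjusted p = 0.729). The ATPase of the glycine betaine transporter (O208_02047) stood at 11942 ± 4827 and 14968 ± 2269. Without the early library of run 2 the value for that ATPase was 0.70 on the log2 scale (limma adjusted p = 0.025). A glycine betaine binding protein, ProX (O208_00343), was called lower in the authors' fit (DESeq2 adjusted p = 0.024).

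Branched-chain amino acid synthesis had the lowest median of any list tested, -2.19, with 7 of 9 members lower (7 adjusted over the list alone; camera adjusted p = 0.00038, adjusted p = 0.743 with an estimated correlation). Its lower members were 6 with the run as a block. On fragment 25, threonine dehydratase (O208_00855) fell from 116 ± 19.7 to 15.9 ± 7.19 (limma adjusted p = 0.00375). Ketol-acid reductoisomerase (O208_00856) fell from 170 ± 28.8 to 25.6 ± 9.91, and the leucine-specific dehydratase large subunit (O208_00862) from 148 ± 48.4 to 18.7 ± 4.46 (limma adjusted p = 0.00246 and 0.00145). The wider list of histidine, aromatic, sulfur and other amino acid synthesis had 15 of 66 members lower and 1 higher (13 and 1 adjusted over the list alone; camera adjusted p = 0.016, adjusted p = 0.767 with an estimated correlation, and 0.128 with the preset correlation without the early library of run 3). In that list, 10 members were lower and 1 higher with the run as a block. Glutamate synthase (O208_00775) fell 3.82-fold, homoserine kinase (O208_00915) 2.22-fold and aspartokinase (O208_02635) 1.89-fold. The exception was cysteine synthase (O208_01754), which rose 2.59-fold (limma adjusted p of these genes 0.00039 to 0.0043). Peptide uptake and peptidases had 8 of 26 members lower, also adjusted over the list alone (4 with the run as a block; camera adjusted p = 0.027, adjusted p = 0.767 with an estimated correlation). Its camera call was lost without the early library of run 1 (0.083). The ATP-binding genes of the oligopeptide transporter, O208_01109 and O208_01110, fell 3.43-fold and 2.65-fold (limma adjusted p = 0.0014 and 0.010). None of the 10 genes listed by product text for the arginine deiminase pathway, which makes ATP and ammonia from arginine, passed, over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05 and 0 with voom; camera adjusted p = 0.675). The list also took in an ornithine carbamoyltransferase gene that lies among arginine synthesis genes on fragment 14 (O208_02569, log2 fold change -1.03, limma adjusted p = 0.664). Arginine deiminase (O208_01594) stood at 691 ± 277 and 699 ± 71.0 and ornithine carbamoyltransferase (O208_01595) at 990 ± 441 and 892 ± 133. The ArcD antiporters O208_01596 and O208_01600 had log2 fold changes of -0.17 and 0.08. The wider amino acid list had 23 lower without the early library of run 2, 7 without the late library of run 1, 8 without that of run 2, and 2 higher without the early library of run 3. Peptide uptake had 5 lower and 1 higher without the early library of run 1, 11 lower and 1 higher without that of run 2, and 4 lower without the late library of run 1 or run 2.

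**Figure D2:**
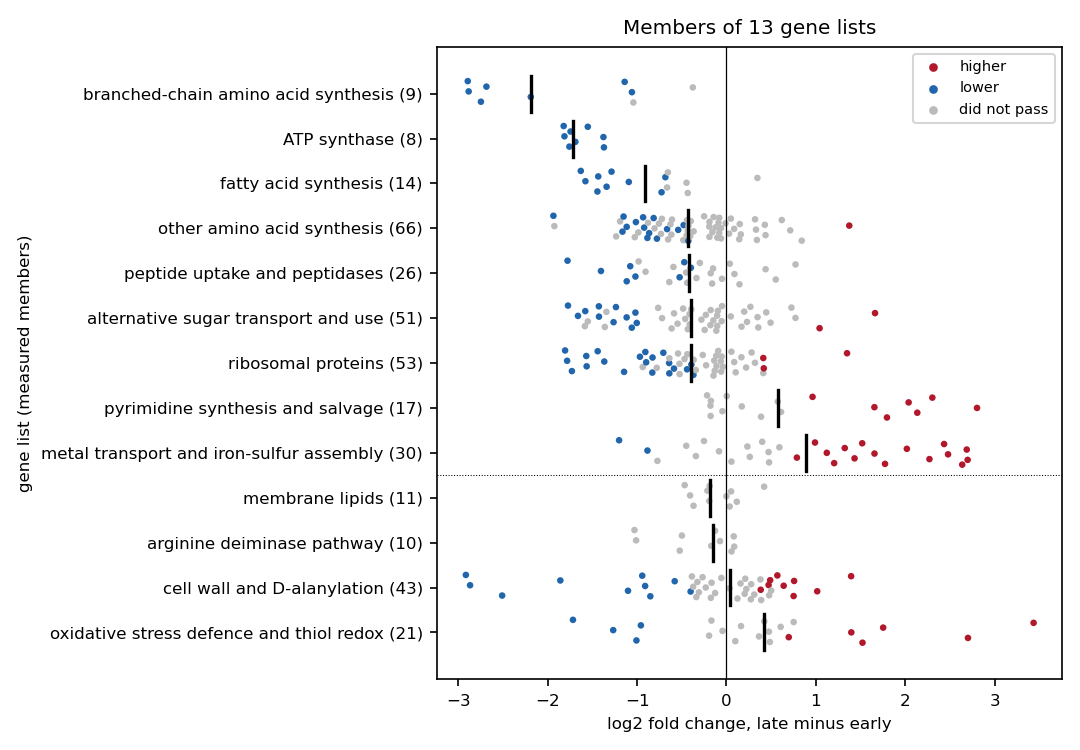
Each point is a member of a gene list, at its log2 fold change of late minus early cells (x), with the lists and their numbers of measured members on the y axis, black bars as list medians, and red and blue points for genes that passed limma at an adjusted p under 0.05 (grey did not). The 9 lists above the dotted line were called by camera with a preset correlation (0 with an estimated correlation), and the 8 ATP synthase genes all lie below 0.

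In the list of cell wall and D-alanylation genes, of 43 members, 9 rose and 10 fell (11 and 10 adjusted over the list alone, 4 and 7 with the run as a block, 2 and 10 with voom; camera adjusted p = 0.790). Its median log2 fold change was 0.03 and its mean -0.18. The dlt genes were its largest falls. DltD (O208_00804, fragment 25, start 139286, end 140573) went from 4295 ± 1276 to 570 ± 65.5. DltB (O208_00802) went from 3940 ± 833 to 690 ± 138, the ligase DltA (O208_00801) from 3270 ± 225 to 908 ± 150 and the carrier protein DltC (O208_00803) from 1014 ± 360 to 130 ± 32.5 (limma adjusted p 0.00055 to 0.0015). The list had 3 higher without the late library of run 1 or run 2 and 2 without that of run 3.

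Pyrimidine synthesis and salvage had 7 of 17 members higher and none lower (8 adjusted over the list alone; camera adjusted p = 0.047, adjusted p = 0.743 with an estimated correlation). The camera call was lost with the run as a block (0.054), where 6 members were higher, and without the early library of run 2 (0.056). The electron transfer and catalytic subunits of dihydroorotate dehydrogenase (O208_00692 and O208_00693) rose 6.97-fold and 4.39-fold, orotate phosphoribosyltransferase (O208_01009) 4.93-fold and the bifunctional regulator PyrR (O208_02329) 3.15-fold (limma adjusted p 0.0023 to 0.0057). Purine synthesis and salvage had 3 of 23 members higher and 0 adjusted over the list alone (camera adjusted p = 0.410). Xanthine permease (O208_02328) rose 3.33-fold (limma adjusted p = 0.017, and 0.068 without the late library of run 2). Among 45 genes of DNA replication and cell division, 16 rose and 4 fell (17 and 5 adjusted over the list alone, 8 and 1 with the run as a block, 10 and 6 with voom; camera adjusted p = 0.063). The set passed without the early library of run 3 (0.033) and with median rescaling (0.048). The class Ib ribonucleotide reductase, which makes deoxyribonucleotides in the presence of oxygen, rose through its alpha subunit (O208_01056, 10566 ± 705 to 23671 ± 3127), its beta subunit (O208_01057, 1.70-fold) and NrdI (O208_01055, 2.83-fold). Gyrase subunit B (O208_00081) rose 1.63-fold (limma adjusted p of these genes 0.00061 to 0.0065). DNA repair and SOS genes had 4 of 29 members higher and 2 adjusted over the list alone (2 with the run as a block, 1 higher and 1 lower with voom; camera adjusted p = 0.184). RecA (O208_01102) had a log2 fold change of 0.24 and did not pass (limma adjusted p = 0.162). Purine genes were higher in 1 case without the late library of run 1 or run 3 and in 0 without that of run 2, with 2 higher and 1 lower without the early library of run 2. Replication genes were 10 higher and 2 lower without the early library of run 1, and 13 and 1 without that of run 3. Without the late libraries of runs 1 to 3 in turn they were 6 and 0, 9 and 1, and 7 and 1. Repair genes were 2 higher and 0 lower without the early library of run 1 and 7 and 1 without that of run 2. Without the late libraries in turn they were 0 and 0, 1 and 0, and 2 and 1.

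Ribosomal proteins had 20 of 53 members lower and 3 higher (24 and 3 adjusted over the list alone, 12 and 1 with the run as a block; camera adjusted p = 0.0022, adjusted p = 0.767 with an estimated correlation). L14p (O208_01542) fell from 2863 ± 133 to 875 ± 321 and L10p (O208_00791) from 2191 ± 290 to 1167 ± 140, whereas S16p (O208_01921) rose from 3499 ± 904 to 8776 ± 1396 (limma adjusted p = 0.0049, 0.0057 and 0.0055). For the 34 translation factors and aminoacyl-tRNA synthetases, 9 fell and 3 rose (11 and 4 adjusted over the list alone, 7 and 1 with the run as a block; camera adjusted p = 0.052). The set passed without the early library of run 2 (0.012), without the late library of run 2 (0.041), with median rescaling (0.047), with quantile normalization (0.024) and with the stricter filter (0.048). The prolyl-tRNA synthetase (O208_00308), next to NADH oxidase O208_00307, fell 3.33-fold and the asparaginyl-tRNA synthetase (O208_00251) 2.60-fold (limma adjusted p = 0.00059 and 0.0020). Chaperones and proteolytic stress proteins had 3 of 20 members higher and 3 lower, as they had adjusted over the list alone (2 and 1 with the run as a block, 2 and 7 with voom; camera adjusted p = 0.790). ClpB (O208_01968), which dissolves protein aggregates, rose from 6098 ± 254 to 12867 ± 1464, and DnaJ (O208_00160) fell 1.69-fold (limma adjusted p = 0.0019 and 0.0082). GroEL (O208_01859), DnaK (O208_01077) and ClpE (O208_00587) had log2 fold changes of -0.47, -0.38 and -0.22 and did not pass. With voom all of them passed in the same direction (limma adjusted p = 0.039, 0.040 and 0.039), as DnaK and ClpE did under quantile normalization (0.048 and 0.024). Of 6 cold shock genes, 2 rose, and 5 did so adjusted over the list alone (1 with voom; camera adjusted p = 0.066, and 0.027 without the late library of run 2). CspB (O208_02110) had a log2 fold change of 0.64 (limma adjusted p = 0.068, 0.046 with the run as a block and 0.027 without the early library of run 1). Ribosomal proteins fell in 12 cases without the early library of run 1 or the late library of run 2 and in 13 without the early library of run 3. Their rises were 1 without the early library of run 3 or any 1 late library. Translation factors and synthetases had 16 lower without the early library of run 2, and 1 higher without the early library of run 1 or any 1 late library. Chaperones had 5 higher and 3 lower without the early library of run 2, and 2 and 1 without any other library. Cold shock genes had 4 higher without the early library of run 2, 1 without the late library of run 2, and 0 without the early library of run 3 or the late library of run 1 or run 3.

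In carbon metabolism, 3 of 18 genes for glycolysis and lactate formation fell, as they did adjusted over the list alone (camera adjusted p = 0.729). The L-lactate dehydrogenase gene with the highest level (O208_00708) stood at 12738 ± 2308 and 11278 ± 1038. The other lactate dehydrogenase genes, O208_01878 and O208_01808, had log2 fold changes of -0.66 and 0.12 and did not pass. In pyruvate dissipation, of 21 genes, 2 rose and 2 fell (2 and 1 adjusted over the list alone and also with the run as a block, 2 and 4 with voom; camera adjusted p = 0.805, median log2 fold change 0.08, mean -0.01). Acetate kinase (O208_01617), which makes ATP from acetyl phosphate, fell from 1369 ± 213 to 470 ± 29.5, and acetolactate decarboxylase (O208_00853), an enzyme of acetoin formation, rose from 5869 ± 994 to 11190 ± 2014 (limma adjusted p = 0.00082 and 0.0098). Pyruvate formate-lyase (O208_02710) had a log2 fold change of 0.02, and 0.44 without the early library of run 2 (limma adjusted p = 0.982 and 0.027). AdhE (O208_02274) stood at 54318 ± 33029 and 24707 ± 6464 (limma adjusted p = 0.123, 0.043 without the early library of run 3 and 0.039 under quantile normalization). Lactose and galactose use had 1 of 19 members higher and 3 lower (1 and 1 adjusted over the list alone, 0 and 1 with the run as a block; camera adjusted p = 0.574). Alternative sugar transport and use had 11 of 51 members lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.767 with an estimated correlation, and 0.105 with the preset correlation without the early library of run 2). The mannose-type sugar phosphotransferase subunits O208_02450, O208_02451 and O208_02452 fell 2.03-fold, 2.36-fold and 2.69-fold (limma adjusted p 0.0025 to 0.0029). Glycogen metabolism had 4 of 6 members lower, also adjusted over the list alone (camera adjusted p = 0.063, and 0.026 without the early library of run 3). Of the glycogen genes, 3 were lower with the run as a block. Glycogen phosphorylase (O208_02674) fell from 11267 ± 135 to 6258 ± 308 and glycogen synthase (O208_02675) 1.51-fold (limma adjusted p = 0.0020 and 0.0084). Citrate and malate use had 1 of 6 members lower and 0 adjusted over the list alone (0 with the run as a block, 2 with voom; camera adjusted p = 0.279, and 0.035 without the early library of run 3). Counts in these lists moved without single libraries. When the early library of run 1 was left out, glycolysis had 1 higher and 2 lower, pyruvate dissipation 2 and 1, lactose use 0 and 0, glycogen 0 and 2 and citrate use 0 and 0. When that of run 2 was left out, glycolysis had 2 higher and 4 lower, pyruvate dissipation 6 and 3, and glycogen 1 and 3. Citrate use had 2 lower without the early library of run 3. Without the late library of run 1, pyruvate dissipation had 1 and 1, lactose use 0 and 0, and alternative sugars 1 and 8. Without that of run 2, glycolysis had 0 and 1, pyruvate dissipation 1 and 1, lactose use 0 and 1, and alternative sugars 2 and 7. Without that of run 3, glycolysis had 0 and 1, pyruvate dissipation 2 and 1, lactose use 1 and 0, and alternative sugars 2 and 7. Glycogen had 2 lower and citrate use 0 without any 1 late library.

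**Figure D3:**
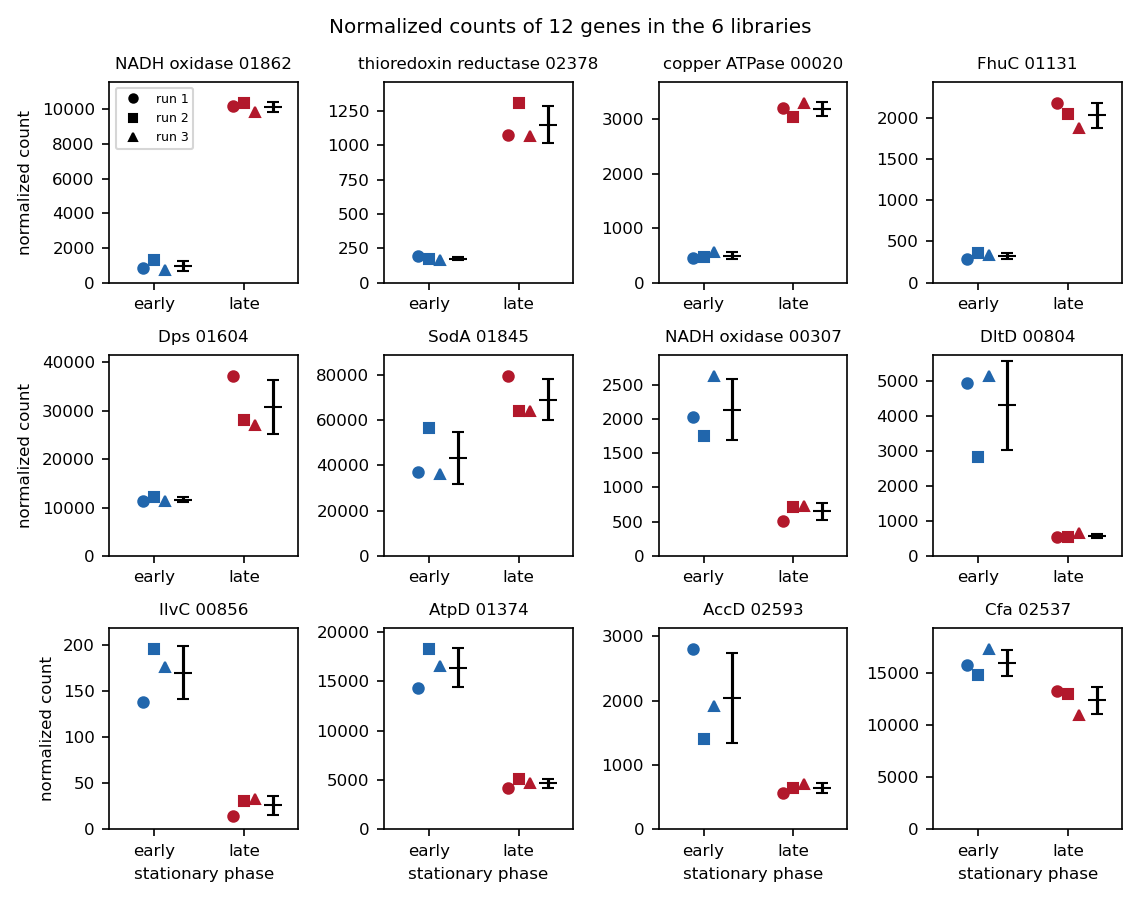
Normalized counts (y) of 12 genes in early and late stationary phase (x), 1 marker per library with its shape giving the fermentation run, and the group mean with its SD (n = 3) as a bar. NADH oxidase O208_01862 had a mean of 963 in early and 10133 in late cells, and NADH oxidase O208_00307 means of 2138 and 649.

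Prophage genes went both ways, with 9 of 60 higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.266, and 0.0084 without the early library of run 2). Phage structural genes on fragment 39 were among those that fell. The portal gene (O208_00267) stood at 69.4, 644 and 52.3 in the early libraries of runs 1 to 3 and at 10.5 ± 4.63 in late cells (log2 fold change -3.64, limma adjusted p = 0.029). Without the early library of run 2 its value was -2.51 (0.0080), and the call was lost without the late library of run 1 (0.099), run 2 (0.073) or run 3 (0.057) and with voom (0.059). The phage proteins O208_00277, O208_00270, O208_00268 and O208_00272 of the same region had log2 fold changes of -3.30, -2.98, -2.96 and -2.95, and of -2.36, -2.00, -1.89 and -2.05 without the early library of run 2 (limma adjusted p 0.0036 to 0.0055). They too lost their calls without any 1 of the late libraries (limma adjusted p 0.056 to 0.107), O208_00268 also without the early library of run 1 (0.051), and O208_00270 and O208_00268 with the run as a block (0.059 each) and under quantile normalization (0.077 and 0.064). O208_00268 was not called with voom either (0.085). A phage antirepressor gene on fragment 34 (O208_02318) rose 3.31-fold (limma adjusted p = 0.0095). Among 10 transposase genes, 3 rose and 1 fell, as they did adjusted over the list alone (0 with the run as a block; camera adjusted p = 0.541), and near-identical copies of such genes can share reads. The list of ribosomal and transfer RNA had 0 measured members and was not tested. None of the 8 competence genes passed, over all genes or adjusted over the list alone (1 lower at an unadjusted p under 0.05 and 0 with voom; camera adjusted p = 0.790, median log2 fold change -0.06, mean 0.03). Of the competence genes, the authors' fit called ComC (O208_01603) higher and ComEB (O208_00937) lower (DESeq2 adjusted p = 0.049 and 0.019). The prophage list had 13 higher and 33 lower without the early library of run 2. Without the late libraries of runs 1 to 3 in turn it had 4 and 1, 5 and 1, and 6 and 1. Transposases had 1 and 0 without the early library of run 1, 3 and 2 without that of run 2, and 2 and 0, 1 and 1, and 1 and 0 without the late libraries in turn.

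The authors' deposited table called 851 of the genes, 427 higher and 424 lower in late cells. Of the 672 genes called here with limma, 578 were among them, each in the same direction. The other 94 genes called here (46 higher, 48 lower) have no p-value in the authors' deposited table, which leaves it empty for 403 genes. Among these are NADH oxidase O208_01862, DltD (O208_00804) and carbon starvation protein A (O208_01844), for which the authors' deposited table lists log2 fold changes of 3.40, -2.91 and 2.67. The 403 genes without a p-value had less even replicates. Their largest deviation of a library from its group mean had a median of 50.5% (lowest 31.6%), against 18.0% in the 1714 other genes. Why the values are empty is not given in the sources used here. The 273 genes called in the authors' deposited table alone did not pass limma here. Among them are cyclopropane fatty acid synthase (O208_02537), FabI (O208_00578) and GroEL (O208_01859), lower there with DESeq2 adjusted p of 0.011, 0.0079 and 0.049. AhpC (O208_01120) and CspB (O208_02110) were called higher there (DESeq2 adjusted p = 0.0074 and 0.016). Across the 2117 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and those computed here had a Pearson correlation of 0.96, and 97.9% had the same sign.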

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

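Of the tests here, limma voom was chosen after the results were seen. Of 111 named genes that passed, 89 kept their call with the run as a block and 100 with voom. Over all 672 called genes, 446 kept it with the block and 581 with voom, each in the same direction. Many named genes were picked by size or adjusted p in these data. No called gene or list among those named reversed direction under any alternative run. With the run as a block as a pairing, 231 genes were higher and 223 lower, 8 lists were called and 22 named genes lost their call, while CspB gained one. Apart from these and the pyrimidine list, the block changed no other limma call of a named gene and no other camera call of a list at the preset correlation. Requiring an absolute log2 fold change of at least 1 left 316 genes (156 higher, 160 lower), 2 lists and 69 named genes. An adjusted p under 0.01 left 331 genes (165 higher, 166 lower), 5 lists and 76 named genes. Stricter thresholds call fewer by construction. No list was called by camera with an estimated correlation (0 lists), against 9 with the preset correlation. Fry, which tests whether the genes of a list move on balance in 1 direction, called 10 lists. These included oxidative stress (adjusted p = 0.034), respiration (0.0025), glycogen (0.031) and DNA replication (0.040), which camera did not call. Of the lists called by camera, fry did not call ribosomal proteins (0.102), alternative sugars (0.067) or the wider amino acid list (0.156). With the run as a block, fry called 2 lists (ATP synthase and metal transport). Branched-chain amino acid synthesis (adjusted p 0.0102 to 0.117), fatty acid synthesis (0.0463 to 0.174) and respiration (0.00249 to 0.108) were among those it no longer called with the block. Leaving out 1 library gave 367 to 932 changed genes, 180 to 453 higher, 187 to 479 lower, 8 to 11 lists and 81 to 108 named genes. The lowest counts of genes came without the late library of run 1 and the highest without the early library of run 2. The cause was not tested. The filter on low values removed no gene, so leaving it out tested nothing. Of the 111 named genes, 34 lost their call without at least 1 library. At this depth, simulated 2-fold changes were recovered for 64 of 100 genes.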

Other observations

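The tests of neighbouring genes and of the 3 single-library patterns were all chosen after the results were seen, whereas the splits of the libraries were planned. Part of the 672 calls fell on neighbouring genes. There were 36 runs of at least 4 adjacent genes called in the same direction, 18 higher and 18 lower, with 203 genes, against at most 6 such runs in 1000 shuffles of gene positions. The shuffles treat neighbouring genes as independent. Genes of a shared operon, such as dlt, are not, so more runs than in the shuffles were likely beforehand and the comparison adds no support. Among the genes in runs, the general stress protein of the Gls24 family (O208_02521) rose from 19207 ± 9283 to 53587 ± 8284 (log2 fold change 1.57, limma adjusted p = 0.0126). The phosphate-binding protein PstS (O208_02464) rose from 9123 ± 1182 to 17897 ± 2175 (log2 fold change 0.97, limma adjusted p = 0.00455) and RepB (O208_00670) 4.03-fold. A run of 13 genes from O208_00057 to O208_00069, with teichoic acid genes among them, had a median log2 fold change of -0.94. The thiol peroxidase gene O208_01158 fell from 4402 ± 831 to 1809 ± 17.4 (log2 fold change -1.27, limma adjusted p = 0.00196), within a run of 8 lower genes. No explanation was tested for these runs.

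The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split called 672 genes, 334 higher and 338 lower, and the highest other split 0 by limma. Counting the real split itself, 1 split gave as many genes in all, 1 as many higher and 1 as many lower. Every other split puts early and late libraries in both groups. A difference by harvest then adds to the spread within groups, so the 0 calls cannot weigh chance. At an unadjusted p under 0.05 the real split had 944 genes and the highest other 100. For gene lists the real split called 9 and the highest other 13, and 6 splits, the real one included, gave at least as many. Among the 4 splits that part all 3 runs, the highest other called 0 genes and 11 lists.

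In the early library of run 1, the 5 riboflavin synthesis genes O208_01032 to O208_01036 had 5.22 to 65.7 normalized counts, a median log2 deviation of -8.22 from the other early libraries. Their recovered reads there were 216 (exact Poisson 95% interval 188 to 247, for counting error only). Low depth of that library is argued against by its 7201135 recovered reads in listed genes, 113% of those in the deepest other library. A difference at the synthesis locus alone is argued against by the riboflavin transporter gene RibU (O208_00786), at a deviation of -4.77, and a difference lasting through the run by the late library of run 1, at a median of -0.10. Without the early library of run 1, the log2 fold changes of the 5 genes ran from -1.03 (O208_01032, limma adjusted p = 0.0146) to -0.45 (O208_01036, 0.0727), and that of RibU was 0.30 (0.286). The adjacent entries O208_01033 and O208_01034 have the same product name and may be parts of a single gene. What caused the low values stays open, and no biological explanation was tested.

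In the late library of run 3, 16 genes of methionine synthesis and uptake had a median log2 deviation of 3.11, and the methionine synthase gene O208_00808 stood at 25389 normalized counts against 76.3 and 80.6. Of the 16 genes, 14 were over 1 higher on the log2 scale, on 5 sequence fragments, which argues against an artifact or copy-number change at a single locus. For the 14 genes other than O208_00808 and its neighbour O208_00809, a median of 0.11 (SD 0.284) in the early library of run 3 argues against a difference lasting through the whole run. That pair stood at 1826 and 1068 there, against 343 and 905, and 158 and 519, in the early libraries of runs 1 and 2 (deviations of 1.71 and 1.89, within 3 SD of those libraries), so for the pair a difference through the run stays open. Without the late library of run 3, the log2 fold changes of the 16 genes ran from -3.41 (O208_00809, limma adjusted p = 0.0275) to 0.16 (O208_02239, 0.533), and no biological explanation was tested.

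In the early library of run 2, phage regions moved apart, with median log2 deviations of 2.96 and 2.63 in regions 1 and 2, -1.64 in region 3 and -1.17 in region 4. A general DNA damage response is argued against by the SOS genes, at a median of -0.21 (SD 0.278 over 9 genes). The cause of the difference stays open, and phage reads from outside and lysis were not tested. Arginine and purine synthesis genes varied among all 3 early libraries, with median normalized counts of 50.7, 173 and 2157 for arginine and 672, 38.4 and 227 for purine synthesis in runs 1 to 3.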
